A study of Melita plumulosa with 40 samples.

How the data were processed

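Gene expression in the amphipod Melita plumulosa, a small sediment-dwelling crustacean, was measured on 40 two-colour Agilent arrays. Per the labels, each array compared total RNA from a pool of 10 exposed animals with RNA from a pool of 10 unexposed animals kept for the same time, and the dyes Cy3 and Cy5 were exchanged on alternate arrays. The 8 treatments had 5 arrays each. RNA was extracted with a phenol-based reagent and cleaned on columns, per the labels' protocols. Whether the unexposed pools of different replicates or treatments were separate pools is not given in the sources used here.

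Per the file headers, the scanner images were read with Agilent Feature Extraction 10.7.3.1. The deposited spot intensities are median signals of the red and green channels with a local background per spot, on a linear scale and not normalised. The deposited scanner log ratio is log10 of red over green after background subtraction and dye normalisation by that software, per the file headers. The series table holds log2 ratios deposited by the authors for the same arrays. Their sizes matched log2 of the processed red over green signal with a largest median difference of 2.91e-07, and column medians lay between -0.10 and 0.08. Of these columns, 39 ran as exposed over unexposed by the dye labels and 1 ran the other way. How the authors tested their comparisons is not given in the sources used here.

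The arrays carried 15744 spots, of which 536 were control spots, for 8512 probes. Of the probes, 6696 had 2 spots and 1816 had 1. The files give probe and contig identifiers without gene names, so the 22 gene lists fixed in advance were not tested and probes are reported by identifier.

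Background was corrected with the normexp method (offset 50) and each array was normalised by loess, with control spots at weight 0 and outlier spots left out, in limma 3.58.1 under R 4.3.3 (with the data.table package, version 1.17.8). The plan had named mean foreground signals, and medians were used because the files hold only those. A second departure from the plan was made after probe counts had been seen. With every local background as deposited, the normexp fit failed on 4 of the 40 arrays, namely ammonia replicate 1, the second array of ammonia replicate 3, and zinc replicates 3 and 4. On these the larger background spread was 254 to 2940 intensity units, against 0.875 to 17.2 on the others, and the median absolute deviation of the log2 ratios was 0.01 to 0.08, against 0.18 to 0.34. Local backgrounds that the scanner software marks as outliers, 607 to 1239 red spots per array, were therefore set to the array median on all arrays. The spread was then at most 4.55 on all arrays and the deviation was 0.23 to 0.26 on those 4. The planned setting is kept as an alternative, and its counts are printed wherever they differ by more than 1.5 times.

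Ratios were turned to exposed over unexposed by the dye labels and spots of a probe were averaged. Probes well above background in either channel on at least 3 arrays were kept, which left 7679. Arrays of the same replicate number within a treatment were averaged, as they carry the same sample label. The repeat arrays correlated across probes with r = 0.774 for bifenthrin replicate 1 and 0.854 for bifenthrin replicate 4. The first array of ammonia replicate 3 was left out, because its dye label and the direction of its deposited ratios disagree and, turned by its label, it had r = -0.728 with its repeat. Of 331 pairs of arrays from different treatments with the same dye orientation, 4 correlated below -0.3. The lowest r was -0.393, between crude oil replicate 3 and the second array of bifenthrin replicate 4. The labels state the dyes, so directions were kept. The fit then held 39 arrays and 37 replicates, with 5 replicates per treatment except 4 for ammonia and 3 for bifenthrin. Fipronil replicates 1 and 3 differed by 1.55 times spot noise, where the next lowest of 76 replicate pairs differed by 6.13 times and the median pair by 66.4 times. The repeat arrays of bifenthrin replicates 4 and 1, with dyes exchanged, differed by 35.1 and 68.4 times, so the fipronil pair (same dye orientation, r = 0.991) was closer than arrays of the same sample. So were other pairs, such as nickel replicates 1 and 3 (6.13 times, same dye orientation, r = 0.957) and copper replicates 5 and 2 (12.2 times, dyes exchanged, r = 0.887). Whether the fipronil and nickel pairs hold separate samples is not settled. They were kept as labelled, and only the fipronil pair was also taken as 1 sample, by its mean, as an alternative.

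One limma model held a mean per treatment and a dye term per probe, with moderated tests (28 residual and 2.12 prior degrees of freedom), two-sided, and Benjamini-Hochberg adjustment over probes at 0.05. Each treatment was tested as its mean log2 ratio against 0. The unexposed RNA entered only as the reference channel, so this test leaves out the spread of the controls themselves as far as replicates shared unexposed pools, which is not given. Contrasts between treatments and classes and a moderated F test over all treatments came from the same model. The metals copper, nickel and zinc, the petroleum products crude oil and diesel, and the insecticides bifenthrin and fipronil formed the classes. Likeness within classes was tested by exact two-sided permutation of the treatments over the classes.

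The rule for named probes, written before the data were examined together with the tests and most alternatives, took gene descriptions where they exist. Without descriptions it names 2 probes higher and 2 lower per treatment, those with the largest mean change among probes past the threshold and of the same sign in every replicate. Channel levels given for single probes are mean log2 signals after loess and quantile normalisation of the average intensity between arrays.

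The number of arrays limits precision. Between 4006 and 7199 probes per array were well above background in the exposed channel (median 6008) and between 4593 and 7145 in the unexposed channel (median 6292), and 0 spots were saturated. The arrays lay on 8 slides and were scanned on 2 occasions, with 23 arrays in scan 1 and 17 in scan 2. A slide held at most 2 arrays of a treatment, so values within single slides were not computed, and slide entered as a block instead. Scan entered as a block and by fits on each scan alone, alternatives chosen after seeing the data. Ammonia had 1 sample in scan 1, and copper and bifenthrin had 1 each in scan 2. Tests of these borrow their spread from the other treatments and assume that the lone sample varies alike.

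The fit was tested on simulated data with 200 of 7662 probes changed. The simulated noise was independent between probes. Real replicates instead shared an axis with 31.5% of the variance left after treatment and dye, so real rates of recovery and false calls may differ. For copper, 65.7% of the probes changed by log2 0.5 were recovered, 97.0% of those changed by 1 and 97.0% of those changed by 2, with 7 false calls among 180. False calls were above 5% for ammonia (19 among 204), zinc (14 among 197), crude oil (10 among 189), copper minus zinc (10 among 176) and diesel minus crude oil (9 among 175). For copper minus zinc the shares were 65.7%, 86.6% and 97.0%, and for diesel minus crude oil they were 65.7%, 89.6% and 93.9%. Other alternatives covered no background correction, the scanner log ratio, median centring, scaling between arrays, the series table, other filters on dim probes, no dye term, arrays as separate replicates, the replicate number as a block, each treatment alone, intensity trend with robust variances, array weights, a fold threshold and each replicate left out.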

Results

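Expression profiles were obtained from pooled Melita plumulosa exposed to 8 contaminants, to ask through which mode each contaminant acts. The exposures were 250 ppb copper, 400 ppb nickel, 400 ppb zinc, 0.3% crude oil, 0.6% diesel, 30 mg per litre ammonia, 100 ppt of the pyrethroid insecticide bifenthrin and 50 ppt of the phenylpyrazole insecticide fipronil. Each value is a log2 ratio of exposed over unexposed animals, so a value of 1 is a doubling. There were 5 replicates per treatment, except 4 for ammonia and 3 for bifenthrin, and 7679 probes were tested. Replicates are separate pools by label. Where pools did not come from separate cultures, the p-values measure only the spread between those samples. The files do not pair the probes with gene names. The reference channel was the only control, and the tests against 0 leave out its own spread as far as replicates shared unexposed pools, which is not given in the sources used here.

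The unexposed channel itself differed between treatments. Over the 39 arrays, component 1 of that channel held 65.1% of the variance and component 2 held 10.3%. The mean squared distance per probe between arrays of a treatment was 0.0834 in the unexposed channel and 0.312 in the exposed channel. Between treatments, the mean unexposed level of the 24 named probes ranged by 1.31 to 8.88 log2 (median 2.51), so a difference in ratio between treatments can lie in either channel.

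**Figure D1:**
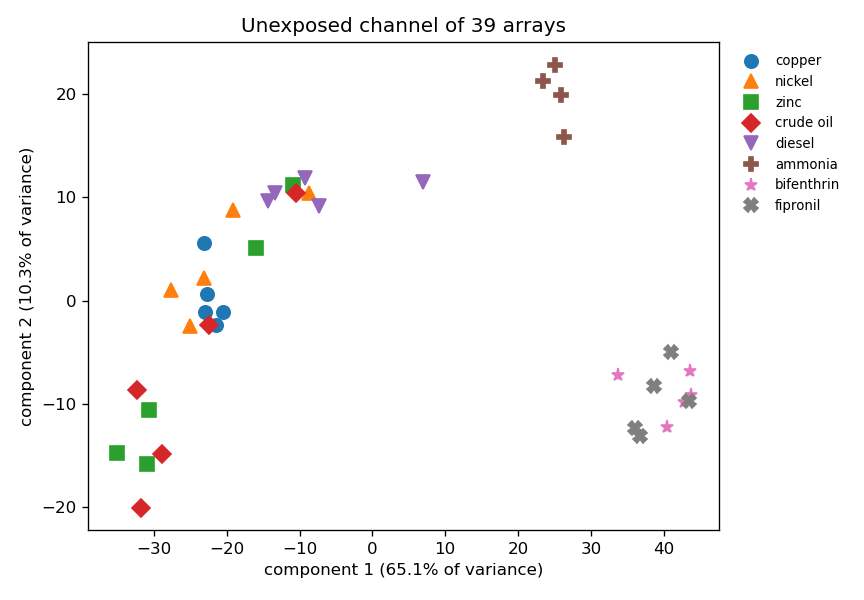
Scores of the unexposed channel of 39 arrays on component 1 (horizontal axis, 65.1% of variance) and component 2 (vertical axis, 10.3%), in arbitrary units, with a symbol per treatment. On component 1 the arrays of bifenthrin and fipronil lay between 33.8 and 43.7, those of ammonia between 23.4 and 26.3, and those of the metals and petroleum products between -35.1 and 6.94.

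Copper lowered CUST_5779_PI428746736, with a log2 ratio of -5.19 ± 0.81 (SE, n = 5, adjusted p = 2.48e-05), or 36.5-fold. CUST_946_PI428746736 was also lower, at -4.75 ± 0.80 (adjusted p = 6.72e-05). CUST_8313_PI428746736 rose by 1.44 ± 0.15 (adjusted p = 1.06e-07) and CUST_5356_PI428746736 by 1.33 ± 0.20 (adjusted p = 1.04e-05). Both were also higher with nickel, zinc, crude oil and diesel (adjusted p at most 0.000241 and 0.00216). All 4 named probes moved the same way in 5 of 5 replicates, as the naming rule requires. CUST_946_PI428746736 was well above background in the exposed channel on 4 of 5 arrays. Among the 20 or 21 other settings run per named probe, left-out replicates apart, the calls of CUST_5356_PI428746736 and CUST_946_PI428746736 ended only in scan 2, on 1 copper sample (adjusted p = 0.0601 and 0.106). The mean unexposed level of CUST_5779_PI428746736 was 15.30 to 15.65 on arrays of the metals and petroleum and 12.11 to 13.06 on those of ammonia and the insecticides, while its exposed level was 10.39 to 12.10 and 10.63 to 13.59. The mean unexposed level of CUST_946_PI428746736 was 12.06 on copper arrays and 6.44 on ammonia arrays. In all, 1617 probes passed the threshold, 655 higher and 962 lower, and 249 of them changed at least 2-fold. Copper gave 1173 probes with slide as a block, 1465 with scan as a block, 776 in scan 1 alone and 81 in scan 2 alone, where it had 1 sample, assumed to vary like those of the other treatments. Median centring in place of loess gave 627, and the count was 922 without replicate 1 and 978 without replicate 3.

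**Figure D2:**
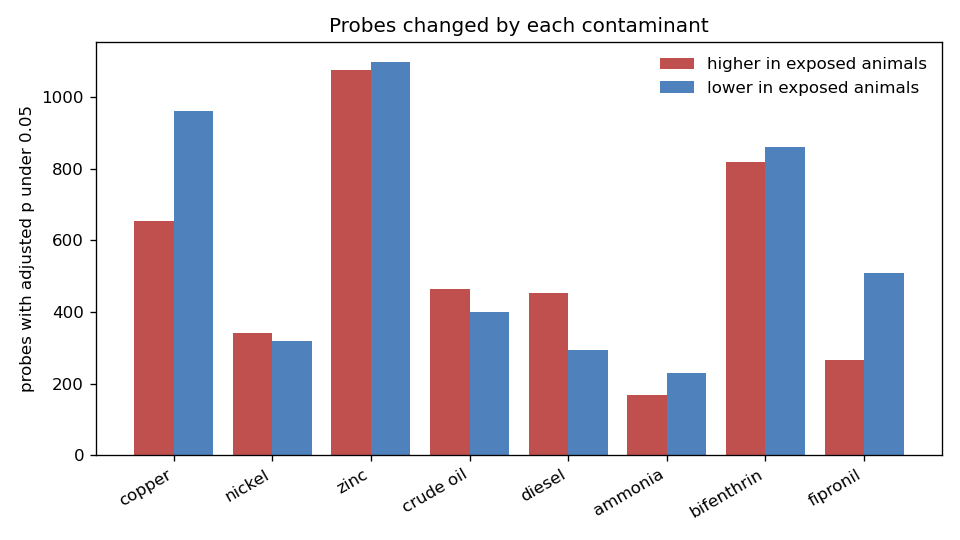
Probes past an adjusted p of 0.05 for each contaminant, with bars for probes higher and lower in exposed than in unexposed animals (vertical axis, number of probes). Zinc had 1075 higher and 1098 lower, while ammonia had 169 and 230.

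Nickel raised CUST_6892_PI428746736 by 6.70 ± 2.08 (SE, n = 5, adjusted p = 0.0393) and CUST_5826_PI428746736 by 6.66 ± 2.12 (adjusted p = 0.0452). Short of the threshold, CUST_6892_PI428746736 stood at 4.76 with zinc, 4.14 with crude oil, 3.70 with diesel and 3.16 with copper. It was negative with ammonia, bifenthrin and fipronil, and CUST_5826_PI428746736 had the same signs. Their moderated F tests between treatments gave adjusted p of 0.0583 and 0.0786, so a change particular to nickel was not shown. In both probes replicate 2 stood apart from the others, at 1.14 and 1.02. CUST_5779_PI428746736 was lower at -4.27 ± 0.81 (adjusted p = 0.000606) and CUST_946_PI428746736 at -3.99 ± 0.80 (adjusted p = 0.00106, exposed channel above background on 3 of 5 arrays). The unexposed level of CUST_6892_PI428746736 was 8.15 on nickel arrays and 16.78 on ammonia arrays. The 660 probes past the threshold were split into 341 higher and 319 lower, and 123 changed at least 2-fold. Nickel gave 364 probes with slide as a block, 634 with scan as a block, 142 in scan 1 and 295 in scan 2. Replicates 1 and 3 were the next most alike pair after that of fipronil (6.13 times spot noise) and were not tested as 1 sample. Median centring gave 180, with 59 higher and 121 lower. Over the other settings the call of CUST_6892_PI428746736 ended under 5 of 20 (adjusted p up to 0.381), CUST_5826_PI428746736 under 7 of 21 (0.386), CUST_5779_PI428746736 under 2 of 21 (0.0754) and CUST_946_PI428746736 under 3 of 20 (0.19). Without replicate 1, 3, 4 or 5 the adjusted p of CUST_6892_PI428746736 was 0.112, 0.116, 0.122 and 0.125, and that of CUST_5826_PI428746736 was 0.124, 0.125, 0.138 and 0.135.

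Zinc lowered CUST_5315_PI428746736 to a log2 ratio of -5.27 ± 0.48 (SE, n = 5, adjusted p = 5.8e-09) and CUST_5779_PI428746736 to -5.24 ± 0.81 (adjusted p = 1.63e-05). CUST_7029_PI428746736 rose by 3.71 ± 0.99 (adjusted p = 0.00525) and CUST_6460_PI428746736 by 3.32 ± 1.09 (adjusted p = 0.0217). Short of the threshold, CUST_6460_PI428746736 stood at 3.32 with nickel (adjusted p = 0.054) and at 1.95 to 2.29 with copper, diesel and crude oil. It stood at 0.17 with bifenthrin, 0.64 with fipronil and -1.87 with ammonia. Its moderated F test between treatments gave an adjusted p of 0.113. CUST_5315_PI428746736 was also lower with copper, at -4.31 (adjusted p = 3.07e-07), with nickel, at -3.23 (adjusted p = 2.83e-05), and with fipronil, at -1.66 (adjusted p = 0.0234). Its unexposed level was 15.89 on zinc arrays and 10.64 on fipronil arrays. The 2173 probes past the threshold were 1075 higher and 1098 lower, and 343 changed at least 2-fold. Zinc gave 1229 probes with the treatment fitted alone, 1884 with slide as a block, 2136 with scan as a block, 615 in scan 1 and 1176 in scan 2. Median centring gave 578 higher and 970 lower. Other settings ended the call of CUST_7029_PI428746736 under 2 of 20 (adjusted p up to 0.361) and that of CUST_6460_PI428746736 under 4 of 21 (0.293). The call of CUST_6460_PI428746736 ended without replicate 3, 4 or 5, at adjusted p of 0.0977, 0.118 and 0.0843.

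**Figure D3:**
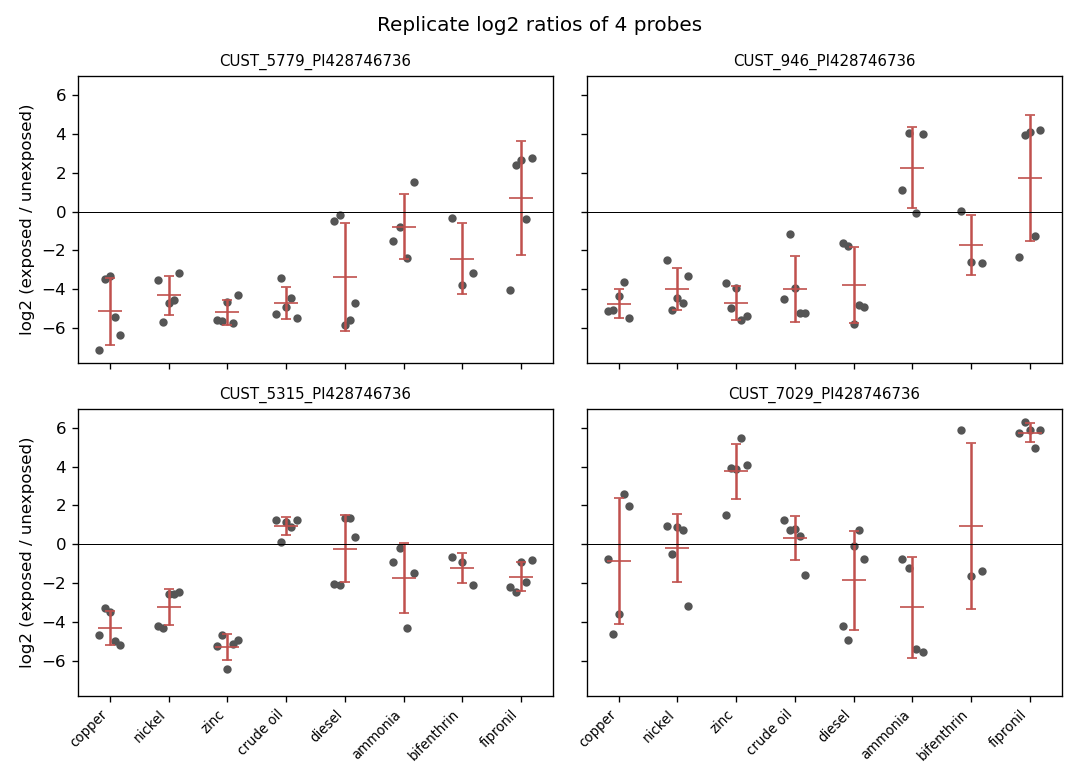
Log2 ratios of exposed over unexposed animals (vertical axis) for 4 named probes in the 8 treatments, picked for drawing after their values were seen, with dots for replicates and red bars for mean ± SD. The replicate means of CUST_5315_PI428746736 lay at -5.28 with zinc, and those of CUST_7029_PI428746736 at 3.77 with zinc and 5.75 with fipronil.

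Crude oil raised CUST_7424_PI428746736 by 2.26 ± 0.36 (SE, n = 5, adjusted p = 4.03e-05), a probe that was lower with copper at -2.80 (adjusted p = 1.42e-06), nickel at -2.17 (adjusted p = 0.00011) and zinc at -2.79 (adjusted p = 9.07e-07). CUST_5596_PI428746736 rose by 1.99 ± 0.23 (adjusted p = 3.21e-07). It was also higher with diesel, at 1.10 (adjusted p = 0.00169), and lower with copper, at -1.02 (adjusted p = 0.00177), and zinc, at -1.60 (adjusted p = 6.16e-06). CUST_5779_PI428746736 was lower at -4.65 ± 0.81 (adjusted p = 0.000174) and CUST_946_PI428746736 at -3.99 ± 0.80 (adjusted p = 0.000864, exposed channel above background on 4 of 5 arrays). The unexposed level of CUST_7424_PI428746736 was 9.97 on crude oil arrays and 6.70 on bifenthrin arrays. Of 865 probes past the threshold, 464 were higher, 401 were lower and 127 changed at least 2-fold. Crude oil gave 834 probes with slide as a block, 823 with scan as a block, 831 in scan 1 and 151 in scan 2. Median centring gave 178 higher and 65 lower, fitting the treatment alone gave 75, and the count was 367 without replicate 2 and 487 without replicate 5. Other settings ended the call of CUST_7424_PI428746736 under 1 of 20 (adjusted p up to 0.0639) and that of CUST_946_PI428746736 under 3 of 20 (0.0712).

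Diesel raised CUST_7723_PI428746736 by 2.30 ± 0.20 (SE, n = 5, adjusted p = 3.27e-09), with replicate 2 apart from the others at 1.43, and CUST_6287_PI428746736 by 2.24 ± 0.34 (adjusted p = 2.19e-05). CUST_7723_PI428746736 was also higher with nickel, at 2.14 (adjusted p = 3.65e-08), crude oil, at 1.96 (adjusted p = 5.07e-08), zinc, at 1.43 (adjusted p = 4.4e-06), and copper, at 1.32 (adjusted p = 1.87e-05). Its mean unexposed level was 10.09 to 10.20 on arrays of the metals and petroleum and 11.95 to 12.12 on those of ammonia and the insecticides. Its exposed level was 11.53 to 12.41 and 11.54 to 12.49, so its difference between these groups of treatments lay mainly in the unexposed channel. CUST_946_PI428746736 was lower at -3.79 ± 0.80 (adjusted p = 0.00169) and CUST_5779_PI428746736 at -3.41 ± 0.81 (adjusted p = 0.00518). The 745 probes past the threshold were 452 higher and 293 lower, with 97 changed at least 2-fold. Diesel gave 558 probes with slide as a block, 728 with scan as a block, 130 in scan 1 and 279 in scan 2. Median centring gave 181, the treatment fitted alone gave 437, and the count was 360 without replicate 4 and 487 without replicate 5. The call of CUST_5779_PI428746736 ended without replicate 4 (adjusted p = 0.0689) and under 3 of 21 other settings (adjusted p up to 0.672), and that of CUST_946_PI428746736 under 2 of 20 (0.39).

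Ammonia raised CUST_5683_PI428746736 by 1.38 ± 0.30 (SE, n = 4, adjusted p = 0.00464) and CUST_6601_PI428746736 by 1.09 ± 0.28 (adjusted p = 0.0201, unexposed channel above background on 3 of 4 arrays). CUST_7727_PI428746736 was lower at -3.998 ± 1.03 (adjusted p = 0.0187, exposed channel above background on 2 of 4 arrays). CUST_5325_PI428746736 was lower at -3.996 ± 1.06 (adjusted p = 0.0233). It was also lower with bifenthrin, at -3.80 (adjusted p = 0.0239), and zinc, at -3.28 (adjusted p = 0.00943). CUST_7727_PI428746736 was also lower with bifenthrin, at -3.71 (adjusted p = 0.0231), copper, at -2.68 (adjusted p = 0.0369), and zinc, at -2.48 (adjusted p = 0.0427). CUST_6601_PI428746736 was lower with crude oil, at -0.98 (adjusted p = 0.0088). CUST_5683_PI428746736 was also higher with diesel, at 2.05 (adjusted p = 2.75e-06), nickel, at 1.49 (adjusted p = 0.000318), and crude oil, at 1.41 (adjusted p = 5e-04), and lower with copper, at -0.77 (adjusted p = 0.0407). The 399 probes past the threshold were 169 higher and 230 lower, and 93 changed at least 2-fold. Ammonia gave 103 probes with slide as a block, 327 with scan as a block, 9 in scan 1, where it had 1 sample, and 162 in scan 2. This count rests on the background handling that was changed after counts were seen: the planned handling gave 3 (693 unadjusted), no background correction 478, scaling between arrays 671, array weights 600, the scanner log ratio 196 and the values of the series table gave 177. It was 83 with the left-out array included as labelled. With that array turned against its dye label the count was 401, of which 334 were shared with the 399. It was 94 with median centring, 0 (limma, 1860 unadjusted) with ammonia fitted alone, 142 without replicate 1 and 241 without replicate 2. Other settings ended the call of CUST_5683_PI428746736 under 7 of 21 (adjusted p up to 0.662), CUST_5325_PI428746736 under 7 of 21 (0.836), CUST_6601_PI428746736 under 9 of 20 (0.727) and CUST_7727_PI428746736 under 9 of 20 (0.578), with each of these highest values from the 1 sample in scan 1. Without replicate 1, 2 or 3 the adjusted p of CUST_7727_PI428746736 was 0.176, 0.133 and 0.0518 and that of CUST_5325_PI428746736 was 0.178, 0.118 and 0.0547, while that of CUST_6601_PI428746736 was 0.202 without replicate 1 and 0.127 without replicate 2.

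Bifenthrin raised CUST_2061_PI428746736 by 2.00 ± 0.26 (SE, n = 3, adjusted p = 2.97e-06) and CUST_3348_PI428746736 by 1.94 ± 0.27 (adjusted p = 5.58e-06). Both were also higher with fipronil, at 0.97 (adjusted p = 0.00168) and 0.96 (adjusted p = 0.0023), and CUST_2061_PI428746736 was lower with crude oil, at -0.79 (adjusted p = 0.00872). The mean unexposed levels of CUST_2061_PI428746736 and CUST_3348_PI428746736 were 9.75 and 8.15 on bifenthrin arrays. On arrays of the metals and petroleum they were 11.7 to 12.2 and 9.82 to 9.98. The exposed levels were 11.69 and 10.04 on bifenthrin arrays, within the 10.98 to 12.53 and 9.25 to 10.10 of metals and petroleum. On fipronil arrays the unexposed levels were 9.81 and 8.07, and the exposed levels were 10.82 and 9.06. CUST_4929_PI428746736 was lower at -4.52 ± 1.48 (adjusted p = 0.026) and CUST_7307_PI428746736 at -4.42 ± 1.45 (adjusted p = 0.0259). CUST_7307_PI428746736 was also lower with zinc, at -4.79 (adjusted p = 0.00169), copper, at -4.14 (adjusted p = 0.0079), and crude oil, at -3.46 (adjusted p = 0.0405). Its moderated F test between treatments gave an adjusted p of 0.328. The 1680 probes past the threshold were 818 higher and 862 lower, and 381 changed at least 2-fold. Bifenthrin gave 1493 probes with slide as a block, 1622 with scan as a block, 1407 in scan 1 and 141 in scan 2, where it had 1 sample. Median centring gave 496 higher and 322 lower, the 5 arrays as separate replicates gave 2600, array weights gave 3143, the treatment fitted alone gave 0 (limma, 1745 unadjusted), and 1069 were called without replicate 1. Other settings ended the calls of CUST_2061_PI428746736 and CUST_3348_PI428746736 under 1 of 21 each (adjusted p up to 0.067 and 0.0681), CUST_4929_PI428746736 under 4 and CUST_7307_PI428746736 under 6. On the 1 bifenthrin sample in scan 2 the log2 ratio was -6.73 for CUST_4929_PI428746736 and -0.70 for CUST_7307_PI428746736. CUST_4929_PI428746736 had adjusted p of 0.178 without replicate 1 and 0.122 without replicate 4, and CUST_7307_PI428746736 had 0.191 without replicate 2 and 0.168 without replicate 4.

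Fipronil raised CUST_7029_PI428746736 by 5.69 ± 0.99 (SE, n = 5, adjusted p = 0.000285), or 51.8-fold, and CUST_5825_PI428746736 by 5.48 ± 1.42 (adjusted p = 0.0107). CUST_7196_PI428746736 was lower at -4.59 ± 0.72 (adjusted p = 8.72e-05) and CUST_924_PI428746736 at -3.40 ± 0.95 (adjusted p = 0.0175). CUST_7196_PI428746736 was also lower with bifenthrin, at -2.81 (adjusted p = 0.0286), ammonia, at -2.66 (adjusted p = 0.0495), copper, at -2.64 (adjusted p = 0.00888), and zinc, at -2.63 (adjusted p = 0.00653). Its moderated F test between treatments gave an adjusted p of 0.155. The unexposed level of CUST_7029_PI428746736 was 8.14 on fipronil arrays and 10.74 on zinc arrays. The 776 probes past the threshold were 266 higher and 510 lower, and 90 changed at least 2-fold. Fipronil gave 621 probes with slide as a block, 756 with scan as a block, 51 in scan 1 and 225 in scan 2. Median centring gave 39 higher and 212 lower, array weights gave 1884, the scanner log ratio gave 501, the series table gave 496, and 510 were called without replicate 1 and 511 without replicate 3. Replicates 1 and 3 were alike beyond any other pair, whether they are separate samples is not settled, and as 1 sample they gave 500. Across 2522 probes, with no dye effect removed, these 2 had r of -0.170 to -0.0531 with replicates 2 and 4, which had the opposite dyes. Replicates 2 and 4 had r = 0.656 with each other. Other settings ended the call of CUST_924_PI428746736 under 5 of 20 (adjusted p up to 0.212), CUST_5825_PI428746736 under 2 (0.343), and CUST_7029_PI428746736 and CUST_7196_PI428746736 under 1 each (0.117 and 0.0965). The call of CUST_924_PI428746736 ended also without replicate 1 (adjusted p = 0.06) or replicate 3 (adjusted p = 0.0574).

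Averaged over the 8 treatments, 2152 probes differed from 0, of which 931 were higher and 1221 lower, and 102 of them by at least 2-fold. The mean over treatments gave 2111 probes with slide as a block, 2142 with scan as a block, 1102 in scan 1 and 1008 in scan 2, with 1 ammonia sample in scan 1 and 1 sample each of copper and bifenthrin in scan 2. The treatments also differed from one another: the moderated F test called 3387 of the 7679 probes. Differences between treatments gave 2680 probes with slide as a block, 3334 with scan as a block, 1312 in scan 1 and 1058 in scan 2, with the same lone samples. Median centring gave 1422 for the mean and 1419 for the F test.

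Among the metals, copper and zinc profiles were close, while nickel differed from both. Copper minus nickel called 670 probes, 144 higher and 526 lower with copper, and 237 of them differed at least 2-fold. Nickel minus zinc called 980 probes, 534 higher and 446 lower with nickel, and 286 differed at least 2-fold. Copper minus zinc called 0 probes in limma, with 300 at an unadjusted p under 0.05 and a smallest adjusted p of 0.134. This does not show that the metals acted alike, but for 7086 probes the 95% interval of the difference lay within 2-fold, and the interval reached 0.23 to either side at the median probe. Copper minus nickel gave 360 probes with slide as a block, 659 with scan as a block, 264 in scan 1 and 11 in scan 2, where copper had 1 sample. Nickel minus zinc gave 375 with slide as a block, 915 with scan as a block, 136 in scan 1 and 113 in scan 2, and copper minus zinc gave 0 in each (305, 281, 260 and 335 unadjusted), the last again with 1 copper sample. Median centring gave 54 for copper minus nickel and 45 higher and 4 lower for nickel minus zinc, which also fell to 600 without nickel replicate 4 and 631 with the planned background handling. Without zinc replicate 2, copper minus zinc called 1 probe, CUST_4867_PI428746736, named after its value was seen (adjusted p = 0.0253).

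Diesel and crude oil differed in 1 probe, CUST_7235_PI428746736, named after its value was seen, which was lower with diesel than with crude oil by a log2 difference of -0.89 ± 0.15 (SE, adjusted p = 0.0144). It stood at 0.38 with diesel (SD 0.41, n = 5) and 1.26 with crude oil (SD 0.41, n = 5). At an unadjusted p under 0.05 there were 627 probes, and for 6940 probes the 95% interval lay within 2-fold. Diesel minus crude oil gave 0 with slide as a block, 1 with scan as a block, 0 in scan 1 and 0 in scan 2 (limma, with 438, 611, 939 and 564 unadjusted). The call count was 0 with the replicate number as a block (626 unadjusted, smallest adjusted p = 0.0517), and 0 with median centring (309 unadjusted), the scanner log ratio (642) or the series table (635). It was 0 without crude oil replicate 2, 4 or 5 (327, 663 and 404 unadjusted) or diesel replicate 1 or 5 (591 and 399 unadjusted), 18 with array weights, 6 without crude oil replicate 3 or diesel replicate 4, 7 without diesel replicate 3 and 58 without crude oil replicate 1.

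The insecticides differed from each other in 593 probes, 351 higher and 242 lower with bifenthrin than with fipronil, and 83 of these differed at least 2-fold. Bifenthrin minus fipronil gave 422 probes with slide as a block, 514 with scan as a block, 108 in scan 1 and 12 in scan 2, where bifenthrin had 1 sample. Array weights gave 2405, arrays as separate replicates gave 1154, the scanner log ratio gave 242 and the series table gave 214. Scaling between arrays gave 381, and leaving out the dye term gave 342. Median centring gave 205 higher and 30 lower, and 328 were called without bifenthrin replicate 1 and 362 without bifenthrin replicate 2.

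Between classes, the metals differed from petroleum in 1871 probes, 856 higher and 1015 lower with metals. The metals differed from the insecticides in 2148 probes, 1034 higher and 1114 lower with metals, and petroleum differed from the insecticides in 2074, 1178 higher and 896 lower with petroleum. At least 2-fold differences were found in 172, 237 and 392 of these probes. Ammonia differed from the mean of the other treatments in 258 probes, 152 higher and 106 lower, and 28 differed at least 2-fold. All of these contrasts except metals minus petroleum crossed sets of treatments with unlike unexposed channels. These sets, joined after the data were seen, were the insecticides, ammonia, and the metals with petroleum. The mean squared distance in the unexposed channel was 0.512 between sets and 0.135 between treatments of a set. Counts for those contrasts may therefore hold differences between references as well as responses. Metals minus petroleum gave 1730 with slide as a block, 1851 with scan as a block, 446 in scan 1 and 1143 in scan 2. Metals minus insecticides gave 1835, 2110, 1025 and 805 in the same order, and petroleum minus insecticides gave 1902, 2060, 1232 and 838. Ammonia minus the others gave 85, 206, 2 (on 1 ammonia sample) and 95. In scan 2 the metals held 1 copper sample and the insecticides 1 bifenthrin sample. Ammonia minus the others was 608 with array weights, 447 with scaling between arrays, 120 with the scanner log ratio and 117 with the series table. With the left-out array included it was 87 as labelled and 202 turned against its dye label. It was 21 with the planned background handling, 90 without ammonia replicate 3 and 147 without ammonia replicate 4. Median centring split metals minus petroleum into 250 higher and 540 lower and ammonia minus the others into 31 and 10.

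On average, treatments of a class resembled each other more than treatments of different classes. Across the 7679 probes, which are not independent replicates, mean log2 ratios correlated with a mean Pearson r of 0.631 over the 5 pairs within a class and 0.201 over the other pairs. The difference of 0.429 had an exact two-sided permutation p of 0.00357 over 840 arrangements, where the smallest possible is 0.00119. All 5 pairs within a class also lay within a single set of treatments with like unexposed channels (the insecticides, or the metals with petroleum). Of the other pairs, 17 crossed such sets, which were joined after the data were seen. The permutation exchanged treatments freely across these sets, so its p cannot tell likeness by class from likeness of the reference. Copper and zinc had r = 0.912 and a covariance of 0.222, with 527 probes called higher in both (91.7 for independent lists), 796 lower in both (138) and 1 opposite (228). Crude oil and diesel had r = 0.668 and a covariance of 0.0780, with 263 higher in both (27.3), 100 lower in both (15.3) and 0 opposite (41.3), while bifenthrin and fipronil had r = 0.585 and a covariance of 0.0983. Nickel had r = 0.437 (covariance 0.0791) with copper and 0.550 (0.117) with zinc. Pairs across classes reached r = 0.643 (0.0924) for nickel and crude oil, 0.651 (0.0840) for nickel and diesel and 0.535 for ammonia and bifenthrin, and r was 0.0893 for copper and diesel and -0.181 for diesel and fipronil. In 100 simulations of unchanged groups, which assumed that a pool varies as much as an exposed replicate, treatments that shared a single unexposed pool had a mean r of 0.834 (highest 0.886) and a covariance of 0.148 (highest 0.208), and treatments with a pool each had 0.00231 and 0.000461. Arrays of a treatment spread less in the unexposed channel, so these values may be too high: with the pool's variance scaled by 0.267, the ratio of those spreads, a shared pool gave a mean r of 0.569 (highest 0.659) and a covariance of 0.0395 (highest 0.0587), in simulations chosen after seeing the data. That ratio does not measure the spread between pools if a treatment's arrays shared a pool. Pool sharing is not given in the sources used here, so part of these likenesses may come from shared references. The difference within over between classes was 0.386 with slide as a block, 0.441 with scan as a block, 0.320 in scan 1 and 0.425 in scan 2, with the same lone samples.

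**Figure D4:**
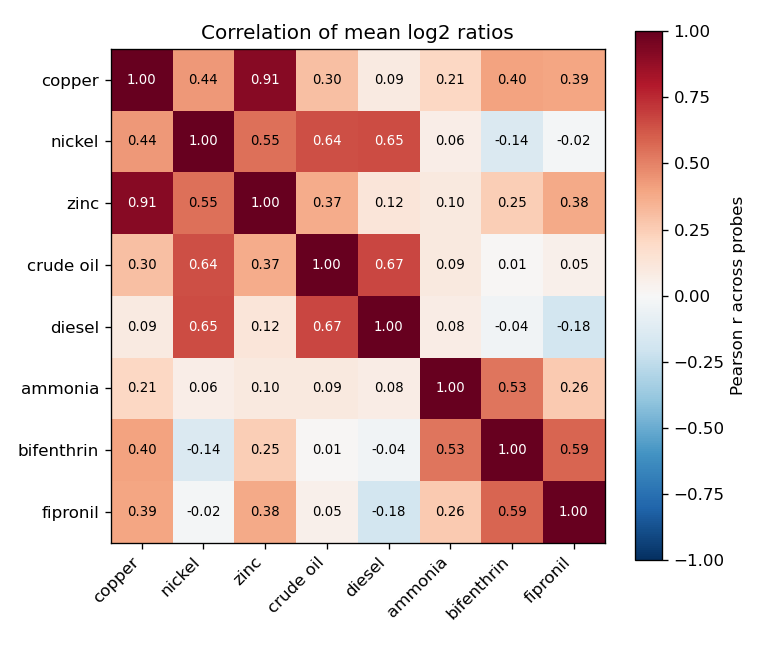
Pearson correlation across probes of mean log2 ratios for each pair of the 8 treatments, with colour and printed value both giving r. Copper and zinc stood at 0.91, and diesel and fipronil at -0.18.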

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

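No test in this part was chosen after its result was seen, though the splits with fipronil replicates 1 and 3 as 1 sample were added after the other splits were seen, and the handling of dye orientation when replicates were turned was corrected after a first set of counts had been seen.

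Of 35 groups of 4 or 5 replicates tested for a replicate far from the rest, 3 held one. Chance gives about 1 in 20 for independent groups, which these were not. Both nickel cases fell on the same replicate, in probes with nearly the same mean log2 ratios (6.70 and 6.66 with nickel). With nickel, replicate 2 stood at 1.14 for CUST_6892_PI428746736 and at 1.02 for CUST_5826_PI428746736, below the other replicates. With diesel, replicate 2 stood at 1.43 for CUST_7723_PI428746736, below the other replicates.

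The log2 ratios of different treatments or classes, which hold both channels, differed by a test of the difference itself in 670 probes for copper minus nickel, 980 for nickel minus zinc, 1 for diesel minus crude oil, 593 for bifenthrin minus fipronil, 1871 for metals minus petroleum, 2148 for metals minus insecticides, 2074 for petroleum minus insecticides and 258 for ammonia minus the others.

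Other splits of the same replicates were counted for each result. For single treatments the replicate ratios were turned in sign. With 16 such splits, or 8 for ammonia and 4 for bifenthrin, a share under 0.05 cannot be reached, and 1 split, the real one, gave as many probes for each treatment. The real count and the highest of the other splits were 1617 and 176 for copper, 660 and 4 for nickel, 2173 and 805 for zinc, 865 and 837 for crude oil, 745 and 136 for diesel, 399 and 4 for ammonia, 1680 and 51 for bifenthrin, and 776 and 108 for fipronil. The crude oil split with 837 turned replicate 1 alone, without which the count was 1159.

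For the contrasts, 100 splits were drawn, or all 56 for bifenthrin minus fipronil. Chance was taken as unlikely, though not excluded, where 1 split, the real one, gave as many. This held for copper minus nickel (670, highest other 125), nickel minus zinc (980, highest other 864), bifenthrin minus fipronil (593, highest other 589), metals minus petroleum (1871, highest other 760), metals minus insecticides (2148, highest other 427), petroleum minus insecticides (2074, highest other 523) and ammonia minus the others (258, highest other 237). It held also for the mean over treatments (2152, highest other 178) and the F test (3387, highest other 3). The highest other count came close to the real one for nickel minus zinc, bifenthrin minus fipronil and ammonia minus the others. For the class contrasts and ammonia minus the others, the splits moved single replicates between treatments, and for the mean they turned single replicates. The real split can then lead through any difference tied to single treatments or their unexposed channels. These splits therefore cannot tell a difference between classes from one between single treatments. All splits used the background handling changed after counts were seen, and the planned handling gave 21 for ammonia minus the others. These splits take fipronil replicates 1 and 3 as separate samples, which is not settled. In splits added after seeing the data, with the 2 as 1 sample, bifenthrin minus fipronil had 35 splits, and 1, the real one, gave as many (444, highest other 136). The same held over 100 splits for metals minus insecticides (2111, highest other 806), petroleum minus insecticides (1952, highest other 523), ammonia minus the others (239, highest other 200), the mean (2077, highest other 256) and the F test (3261, highest other 162). Fipronil itself then had 8 splits, too few for a share under 0.05 (500, highest other 13). The highest nickel minus zinc split exchanged zinc replicate 1 with nickel replicate 5, both from scan 2, and the count with scan as a block was 915. For copper minus zinc the real count was 0 in limma (300 at an unadjusted p under 0.05), so all 100 of 100 splits gave at least as many by definition and tell nothing of chance, and the highest other gave 11. For diesel minus crude oil, 11 of 100 splits gave at least 1 probe, so chance is not made unlikely there. Its highest other split, with 259 probes, called many times the real count, which points to a structure among the replicates.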

How the results depend on the processing

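The alternatives chosen only after seeing the data were the background handling planned before, the treatment of the ammonia array, fipronil replicates 1 and 3 as 1 sample, and scan as a block or alone. Named probes were picked for large changes of the same sign in every replicate, so their direction could hardly reverse. Of 806 values under the alternatives run, 693 stayed past the threshold, 113 did not and 0 reversed, and 34 of those 113 came from single scans. This leaves out quantile normalisation of average intensity, which fixes the ratios. Of 12 values from a scan with 1 sample of the treatment, 8 did not stay past it. The likeness within classes stayed on its side of the threshold in all alternatives run, from 0.310 to 0.573, with exact p from 0.00119 to 0.0238. Copper minus zinc stayed at 0 in limma outside the left-out replicates, with 59 with median centring to 498 with array weights at an unadjusted p under 0.05. Counts within 1.5 times of those reported are not repeated. The cause of the other shifts was not tested, except that fits with fewer samples or probes, or with a fold threshold added, have less to call by construction.

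The scanner log ratio gave 196 for ammonia, 501 for fipronil, 0 for diesel minus crude oil, 242 for bifenthrin minus fipronil and 120 for ammonia minus the others. Median centring in place of loess gave 627 for copper, 180 for nickel, 243 for crude oil, 181 for diesel, 94 for ammonia, 818 for bifenthrin, 251 for fipronil, 1422 for the mean, 54 for copper minus nickel, 49 for nickel minus zinc, 0 for diesel minus crude oil, 235 for bifenthrin minus fipronil, 790 for metals minus petroleum, 1084 for metals minus insecticides, 884 for petroleum minus insecticides, 41 for ammonia minus the others and 1419 for the F test. Scaling between arrays gave 671 for ammonia, 381 for bifenthrin minus fipronil and 447 for ammonia minus the others. The series table gave 177 for ammonia, 496 for fipronil, 0 for diesel minus crude oil, 214 for bifenthrin minus fipronil and 117 for ammonia minus the others. The strict filter on dim probes, which left 3441, gave 156 for ammonia, 909 for bifenthrin, 411 for fipronil, 1382 for the mean, 0 for diesel minus crude oil, 297 for bifenthrin minus fipronil, 1316 for metals minus insecticides, 1272 for petroleum minus insecticides and 111 for ammonia minus the others. Without a dye term the count was 342 for bifenthrin minus fipronil. Arrays taken as separate replicates gave 2600 for bifenthrin and 1154 for bifenthrin minus fipronil. The replicate block gave 0 for diesel minus crude oil. Slide as a block gave 364 for nickel, 103 for ammonia, 360 for copper minus nickel, 375 for nickel minus zinc, 0 for diesel minus crude oil and 85 for ammonia minus the others. Each treatment fitted alone, with fewer samples per fit, gave 1229 for zinc, 75 for crude oil, 437 for diesel, 0 for ammonia (1860 unadjusted) and 0 for bifenthrin (1745 unadjusted). Array weights gave 600 for ammonia, 3143 for bifenthrin, 1884 for fipronil, 18 for diesel minus crude oil, 2405 for bifenthrin minus fipronil and 608 for ammonia minus the others. The planned background handling gave 3 for ammonia, 631 for nickel minus zinc and 21 for ammonia minus the others. The ammonia array included as labelled gave 83 for ammonia and 87 for ammonia minus the others. Turned against its dye label it gave 401 and 202. Fipronil replicates 1 and 3 as 1 sample gave 500 for fipronil. Scan 1 alone, with fewer samples and 1 for ammonia, gave 776 for copper, 142 for nickel, 615 for zinc, 130 for diesel, 9 for ammonia, 51 for fipronil, 1102 for the mean, 264 for copper minus nickel, 136 for nickel minus zinc, 0 for diesel minus crude oil, 108 for bifenthrin minus fipronil, 446 for metals minus petroleum, 1025 for metals minus insecticides, 1232 for petroleum minus insecticides, 2 for ammonia minus the others and 1312 for the F test. Scan 2 alone, with fewer samples and 1 each for copper and bifenthrin, gave 81 for copper, 295 for nickel, 1176 for zinc, 151 for crude oil, 279 for diesel, 162 for ammonia, 141 for bifenthrin, 225 for fipronil, 1008 for the mean, 11 for copper minus nickel, 113 for nickel minus zinc, 0 for diesel minus crude oil, 12 for bifenthrin minus fipronil, 1143 for metals minus petroleum, 805 for metals minus insecticides, 838 for petroleum minus insecticides, 95 for ammonia minus the others and 1058 for the F test. A threshold of at least 1.5-fold gave 673 for copper, 287 for nickel, 950 for zinc, 333 for crude oil, 286 for diesel, 166 for ammonia, 681 for bifenthrin, 214 for fipronil, 265 for the mean, 645 for nickel minus zinc, 261 for bifenthrin minus fipronil, 681 for metals minus petroleum, 616 for metals minus insecticides, 762 for petroleum minus insecticides and 92 for ammonia minus the others.

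With each replicate left out in turn, counts ranged from 922 to 1564 for copper, 1943 to 2282 for the mean, 493 to 866 for copper minus nickel, 0 to 1 for copper minus zinc, 1651 to 1996 for metals minus petroleum, 1523 to 2313 for metals minus insecticides, 90 to 317 for ammonia minus the others, 3081 to 3550 for the F test, 465 to 595 for nickel, 600 to 1157 for nickel minus zinc, 367 to 1159 for crude oil, 0 to 58 for diesel minus crude oil, 1772 to 2102 for petroleum minus insecticides, 142 to 303 for ammonia, 360 to 717 for diesel, 1069 to 1301 for bifenthrin, 328 to 613 for bifenthrin minus fipronil, 510 to 697 for fipronil and 1537 to 2022 for zinc. The replicates behind shifts of more than 1.5 times stand in the report. The difference of mean r within classes ranged from 0.397 to 0.468 with a replicate left out, and from 0.374 (without zinc) to 0.531 (without nickel) with a treatment left out.

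By median correlation, replicate numbers did not pair the samples. Same-numbered replicates of different treatments had a median correlation of deviations of -0.00807 over 120 pairs, against 0.0329 over 477 pairs with different numbers. Of 37 replicates, 12 correlated best with their own number, which was not tested against chance, so some pairing is not excluded. With the replicate block, copper gave 1638 probes, zinc 2194, nickel 648, crude oil 847, diesel 764, ammonia 355, bifenthrin 1476 and fipronil 774, and it changed no count by more than 1.5 times except diesel minus crude oil. Quantile normalisation of average intensity left the log ratios as they were and so tested nothing. The gene list alternatives were not run. Signal over background limited the strict filter to 3441 of 7679 probes.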

Other observations

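The tests of leakage as the whole cause, of a pool shared alike, of slide or dye for copper and zinc, and of pool spread and slide for the replicate axis were chosen only after their results were seen, as were all 95% intervals.

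Some probes were called in most treatments. In at least 5 of the 8 treatments, 98 probes were called in a single direction, 41 higher and 57 lower, where 1000 shufflings of the call lists gave a mean of 0.867 and at most 4. A further 100 were called in at least 5 treatments but in both directions (mean of shuffled lists 12.9, highest 25). Shuffled lists leave out any sharing of unexposed pools between treatments. They also leave out the likeness of treatments such as copper and zinc (r = 0.912). The metals and petroleum treatments had like unexposed channels, so an unusual reference level could give calls in all of them. More calls than in shuffled lists therefore do not show a response common to the contaminants.

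The unexposed channel fell into sets of treatments, joined here after the data were seen: the insecticides, ammonia, and the metals with petroleum. The mean squared distance was 0.135 between treatments of a set and 0.512 between sets. On single slides the distance between sets was 4.28 times that within a set (95% interval 2.87 to 6.37), which argues against slide. The steepest slope of unexposed on exposed differences within a set was 1.21 times the flattest between sets, so exposed signal leaking into the other channel may contribute. Differences between sets had 1.23 times the variance in the unexposed channel (median, 12 of 17 pairs above 1). The 95% intervals, from 0.990 and 0.991, were by themselves too wide to exclude leakage as the whole cause. A leak alike on all arrays would also carry exposed differences within sets. There the variance in the unexposed channel was at most 0.724 of that in the exposed channel. Along the replicate axis described below it was 0.0308 of it (95% interval 0.0166 to 0.0571). These values argue against a leak alike on all arrays as the whole cause. Leakage as part of the cause, and separate unexposed pools for different exposure times (untested), remain open.

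The likeness of copper and zinc (r = 0.912) could come from a shared unexposed pool. Simulated unchanged groups with a shared pool reached r = 0.886 and a covariance of 0.208 under an assumed pool spread, and 0.659 and 0.0587 under the measured unexposed spread; the observed covariance was 0.222, but simulated bounds exclude nothing. In the exposed channel alone, copper minus crude oil and zinc minus fipronil had r = -0.0226, which goes with a shared pool as the whole cause, though r ran from -0.135 to 0.763 over 30 choices of subtracted treatments (median 0.511), and from 0.527 to 0.751 over the 6, chosen after seeing the data, with both from the set of metals with petroleum. A pool shared alike by copper, nickel, zinc and crude oil would give their pairs like covariances, and the highest other was 0.529 of that of copper and zinc (0.423 to 0.619 with replicates left out), with a 95% interval of 0.242 to 1.16 that does not exclude it. Copper and zinc arrays on other slides with opposite dyes had a median r of 0.542 over 12 pairs (95% interval 0.416 to 0.647), which argues against slide or dye, while a pool shared by copper and zinc, with or without others, and a like response to both metals remain open.

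Replicates of a treatment spread along an axis that held 31.5% of the variance left after treatment and dye, against 15.0% for the next. Variance along it in the unexposed channel was 0.0308 of that in the exposed channel (95% interval 0.0166 to 0.0571), which argues against the spread of the unexposed pools. Slides accounted for 0.185 of it (permuted mean 0.194, permutation p = 0.485, upper 95% limit 0.266), which argues against slide as the main source. Its position followed the median exposed signal weakly over 37 replicates (Pearson r = 0.278, permutation p = 0.0971; Spearman rho = 0.315, permutation p = 0.0582; r = 0.297 without the 2 most distant samples), a squared correlation of 0.0770 with a 95% limit of 0.305, past the 0.25 set in advance. Signal strength remains open, and no biological explanation was tested.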
